A study of Mus musculus with 15 samples.

How the data were processed

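Cerebral vessels were prepared, per the labels' protocols, from mice perfused with cold phosphate-buffered saline. The brains were cleared of pia mater and choroid plexus and homogenised in sucrose buffer, and repeated low-speed spins removed myelin, neurons and detached cells. RNA libraries followed standard Illumina protocols; strandedness and the counting step are not given in the sources used here. The submitters' processing notes name STAR 2.5.1b and the genome build mm8.

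The authors deposited a table of FPKM values (fragments per kilobase of transcript, scaled to the number of mapped fragments) for 22557 genes in 15 libraries, per the file headers. None of its values is exactly 0 and 5.99% lie below 0, which FPKM cannot do. Of those, 92.8% lie above -0.001 and the lowest is -0.465, for Hba-ps4. The step that produced them is not given in the sources used here, and values below 0 were set to 0. FPKM already corrects for library size and gene length, so no further scaling was applied in the main fits. The authors also deposited tables of differential genes holding log2 fold changes and p-values with q-values for 2 contrasts. All genes in them have an absolute log2 fold change above 1 and a q-value below 0.05; the test behind them is not given in the sources used here.

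Gene identifiers were matched to GENCODE M21 (GRCm38) for lengths and positions (22419 of 22557 genes). The authors' files hold no coordinates, so every position is that of GRCm38 and none was converted from the build in the notes. Rows sharing a symbol (31 symbols) were summed, leaving 22526 symbols. Reads were estimated by multiplying FPKM by exon length; among values of up to 10 reads, 42.7% (GFP-AL replicate 3) to 65.3% were whole within 0.1 read, against 20% by chance. The size of a single read gave the depth per library, 13.5 to 31.6 M fragments. These reads were not whole often enough for a count test, so the main test does not use them; depth served as a description and as a covariate, and the estimated reads were used in an alternative fit with voom.

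Groups were taken from the library titles. The main test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with group means over all 15 libraries, empirical Bayes with an intensity trend, and 13082 genes with a mean of at least 1 FPKM over all libraries. P-values were adjusted by the Benjamini-Hochberg method within a comparison, and genes with adjusted p below 0.05 were called. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. The main test, the comparisons, the 35 gene lists and the naming rule were fixed before the data were examined; smaller marker sets for resident microglia, blood-derived myeloid cells, activated endothelium, clock genes and cold-induced genes were added later.

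Named genes were Plod3, Plod1, Plod2, Col4a1 and Col4a2, and per comparison the 10 highest and 10 lowest log2 fold changes among called genes whose groups did not overlap, leaving out predicted genes and small RNAs. Up to 4 called members of a list were named, smallest p first; Some genes that the rule selects are not reported here. Ttr falls outside this rule and was chosen after its values were seen. For the move back, the 10 genes called in both comparisons in opposite directions with the largest change were named. Of the named genes, 19 have an exon that overlaps another annotated gene.

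The 35 gene lists were tested with camera (preset correlation 0.01, and with an estimated correlation) and with fry, adjusted over the lists within a comparison. Across the 35 lists camera called 16 in GFP-AL against GFP-Veh, 15 in LH3-AL against GFP-AL and 13 in LH3-AL against GFP-Veh. With an estimated correlation it called 0, 4 and 1. Fry, which tests whether the genes of a list move one way on balance and does not compare them with other genes, called 13, 13 and 2. Plod3 was also tested by an exact two-sided permutation of the assignments of 10 libraries.

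The opposite-sign share was set against 20 simulations with unchanged groups, 20 with LH3-AL equal to GFP-AL, and 20 splits of the GFP-AL libraries. In these simulations and those below, noise was drawn independently for each gene, so shifts that many genes share in a library are absent. Scripts were tested on simulated data drawn from the real means and spreads with 200 genes changed in GFP-AL. In GFP-AL against GFP-Veh (13082 genes) 37.5% of genes changed by 0.5 on the log2 scale, 91.9% of those changed by 1 and 100% of those changed by 2 were recovered, with 10 of 12882 unchanged genes called. In LH3-AL against GFP-AL (13082 genes) the shares were 48.2%, 91.9% and 100%, with 4 unchanged genes called, and no gene was called in LH3-AL against GFP-Veh, where none was changed. Camera gave p below 0.05 for 20 of 20 raised lists and 4 of 100 unchanged ones in GFP-AL against GFP-Veh (13082 genes).

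Alternatives were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, median-of-ratios scaling, quantile normalization, only the 2 groups compared, the replicate number as a factor, array weights, no trend, at least 1.5-fold, and each library left out in turn. Added after seeing the data were log2 depth as a covariate, voom on estimated reads, and fits without 2 or 3 libraries that stood apart. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for tables and plots. No library was left out of the main fits.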

Results

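Gene expression was measured by bulk RNA sequencing in cerebral vessels isolated from C57BL/6 mice aged 8 months. The 15 libraries fell into 3 groups of 5. GFP-Veh mice received an adeno-associated virus (AAV) carrying green fluorescent protein by stereotactic injection, then saline. GFP-AL mice received the same virus, then angiotensin II together with L-NAME, an inhibitor of nitric oxide synthase; the pair of drugs raises blood pressure and the series concerns spontaneous intracerebral haemorrhage in such mice. LH3-AL mice received an AAV carrying LH3, the lysyl hydroxylase encoded by Plod3, and the same drugs. No group received the LH3 virus and saline. Depth estimated from the smallest steps between low values was 13.5 to 16.0 M fragments (M, mega) in GFP-Veh replicates 1 to 4 and 29.8 M in GFP-Veh replicate 5. It was 21.2 to 27.8 M in GFP-AL and 18.04 to 31.6 M in LH3-AL. The labels treat each library as a separate sample of its group, and whether each came from its own mouse is not stated. P-values of the main fit therefore rest on the spread between these samples, estimated over all 3 groups.

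GFP-AL libraries stood apart from both other groups. On the first principal component of log2(FPKM + 1), which held 43.6% of the variance over 13082 genes, GFP-AL scored 19.8 to 58.0, GFP-Veh -27.1 to -4.13 and LH3-AL -26.9 to -6.44. GFP-AL replicates 2 and 3 lay farthest out, at 49.4 and 58.0. GFP-AL replicate 3 also had the fewest genes at 1 FPKM or more (11965, against 12450 to 13462 in the other libraries) and the largest share of reads from 4 globin genes (1.49%). GFP-Veh replicate 2 scored -33.8 on the third component and had the highest Ttr share of reads (1.15%). Correlations within a group ran from 0.948 to 0.982 in GFP-Veh, from 0.932 to 0.970 in GFP-AL and from 0.960 to 0.987 in LH3-AL.

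**Figure D1:**
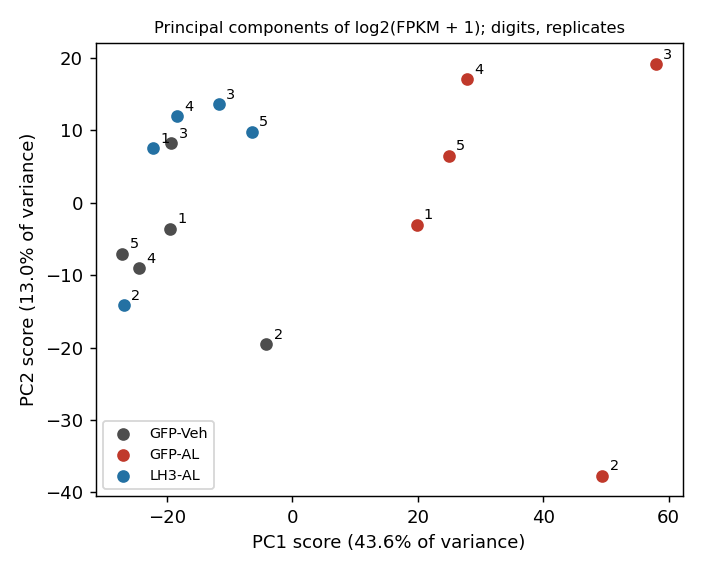
Scores of the 15 libraries on the first and second principal components of log2(FPKM + 1), with the percent of variance on each axis; colours mark groups and digits replicates. The 5 GFP-AL libraries sit at 19.8 or more on PC1 and the other 10 at -4.13 or less.

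The transferred gene was examined before any other. Plod3 (ENSMUSG00000004846, chromosome 5, 136987019 to 136996648, plus strand, GRCm38) averaged 16.8 ± 0.621 FPKM in GFP-Veh, 13.9 ± 1.09 in GFP-AL and 21.6 ± 1.46 in LH3-AL (SD, n = 5). It was 0.60 ± 0.08 (SE) higher on the log2 scale in LH3-AL than in GFP-AL (limma adjusted p = 1.07e-04), with no overlap between the 5 libraries of each group (two-sided exact permutation p = 0.00794, the smallest that the assignments of 10 libraries can give). Against GFP-Veh, Plod3 fell by 0.25 ± 0.08 in GFP-AL (adjusted p = 0.0216), a call that was lost with median-of-ratios scaling (-0.16, adjusted p = 0.156), in a fit of only these 2 groups (0.0585), with log2 depth as a covariate (0.0988), and without GFP-Veh replicate 4 (0.0573) or GFP-AL replicate 1 (0.0524). Plod3 did not overlap between the 5 libraries of these groups either (exact permutation p = 0.00794). In LH3-AL it was 0.34 ± 0.08 above GFP-Veh and missed the threshold (adjusted p = 0.0628). There too the 5 libraries of each group did not overlap and the exact permutation p was 0.00794. The related lysyl hydroxylases Plod1 and Plod2 passed in no comparison, with log2 differences of -0.01 and 0.13 between LH3-AL and GFP-AL. Whether the vector carries mouse or other sequence is not given in the sources used here, so endogenous and vector transcripts were not separated. Exons of Plod3 overlap those of Znhit1 on the opposite strand.

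Both chains of the main collagen of vascular basement membranes followed the same course. Col4a1 averaged 101.5 ± 3.38 FPKM in GFP-Veh, 45.1 ± 3.66 in GFP-AL and 116 ± 32.9 in LH3-AL (SD, n = 5). Col4a2 averaged 70.6 ± 3.29, 35.5 ± 10.4 and 99.5 ± 27.6 FPKM. In GFP-AL against GFP-Veh they fell by 1.16 ± 0.14 and 1.01 ± 0.18 (SE; limma adjusted p = 4.43e-05 and 8.41e-04), and in LH3-AL against GFP-AL they rose by 1.31 ± 0.14 and 1.46 ± 0.18 (adjusted p = 3.48e-05 and 8.68e-05). LH3-AL differed from GFP-Veh by 0.15 ± 0.14 and 0.45 ± 0.18, neither past the threshold (adjusted p = 0.800 and 0.446). The genes lie head to head on chromosome 8 (Col4a1, 11198423 to 11312826, minus strand; Col4a2, 11312805 to 11449287, plus strand) and their annotated exons overlap.

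**Figure D2:**
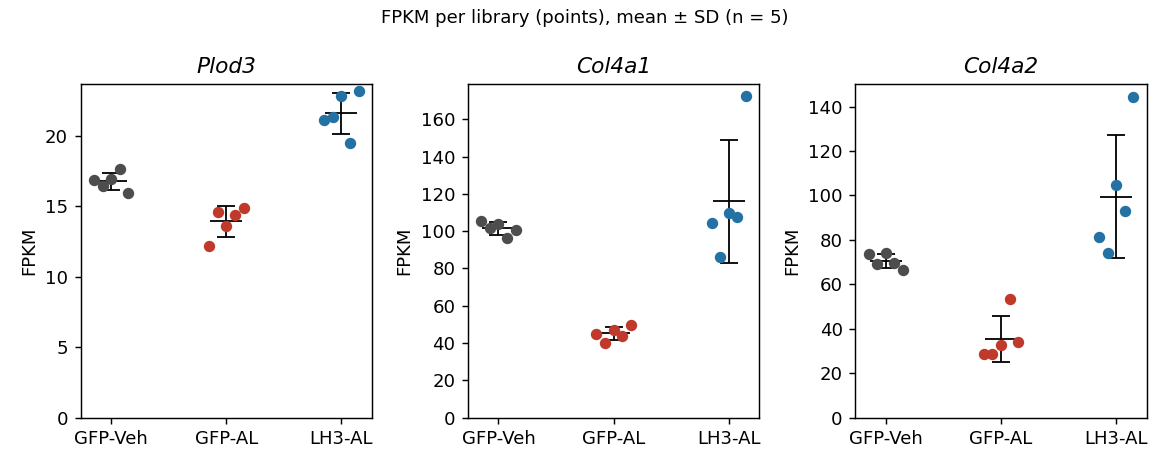
FPKM of Plod3, Col4a1 and Col4a2 in each library (points) with the group mean and SD (n = 5). Plod3 is highest in LH3-AL (mean 21.6), and Col4a1 is lowest in GFP-AL (mean 45.1) and spreads widely in LH3-AL (SD 32.9).

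GFP-AL against GFP-Veh asked what angiotensin II with L-NAME did to cerebral vessels under the control virus. The largest gains included acute-phase and inflammatory genes. Lcn2, an iron-sequestering acute-phase protein, averaged 4.72 ± 2.20 FPKM in GFP-Veh and 213 ± 155 in GFP-AL (log2 fold change 5.00 ± 0.59, SE). The protease inhibitor Serpina3n went from 10.4 ± 2.52 to 311 ± 49.6 FPKM (4.79 ± 0.42) and the secreted glycoprotein Lrg1 from 17.3 ± 13.7 to 433 ± 203 (4.72 ± 0.45). Ch25h, which makes 25-hydroxycholesterol, rose by 4.38 ± 0.35, the lipopolysaccharide co-receptor Cd14 by 3.87 ± 0.32, the cytokine-signalling inhibitor Socs3 by 3.80 ± 0.33, and the venular chemokine receptor Ackr1 by 3.53 ± 0.39. Tnfsf8, the matrix protease Adamts9 and the chitinase-like protein Chil3 completed the 10 highest, with gains of 3.52, 3.50 and 3.47.

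Other genes fell strongly in GFP-AL. Gkn3 fell from 141 ± 53.1 to 10.1 ± 3.75 FPKM (log2 fold change -3.67 ± 0.34), the BMP and Wnt antagonist Sostdc1 from 27.3 ± 7.03 to 3.995 ± 1.33 (-2.51 ± 0.21), and alkaline phosphatase Alpl from 87.5 ± 17.1 to 14.9 ± 3.71 (-2.49 ± 0.21). Cyp2e1 (-2.57), Slc26a10 (-2.40), the potassium channel subunit Kcne2 (-2.32), Akr1c14 (-2.19), Myoc (-2.18), Tnfrsf25 (-2.09) and the sphingosine-1-phosphate phosphatase Sgpp2 (-2.04) made up the rest of the 10 lowest. All 20 genes passed with limma adjusted p of at most 2.54e-04. Over 13082 genes, 3737 passed an adjusted p of 0.05, 1416 higher and 2321 lower, and 1854 of them changed at least 1.5-fold. The groups did not overlap at 2183 genes (16.7%; chance gives 0.79%). With median-of-ratios scaling the split became 1842 higher and 1711 lower, so the larger number of lower genes depends on the scaling. With log2 depth as a covariate 2352 genes passed, and with the 3 libraries that stood apart left out (GFP-AL replicates 2 and 3, GFP-Veh replicate 2) 3425 passed; both settings were chosen after seeing the data.

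Inflammatory genes rose as a group in GFP-AL. Of 25 tested genes of inflammation and leukocyte adhesion 20 were higher and 1 lower (the same counts when adjusted over the list alone), led by Ch25h, Socs3, Cebpd (2.52) and Il4ra (2.35); the list passed camera (adjusted p = 1.99e-15; adjusted p = 0.0504 with an estimated correlation). Of 19 microglia and macrophage markers 14 were higher and none lower, both over all genes and when adjusted over the list alone, among them the lysosomal Cd68 (1.20), the integrin Itgam (1.34), the cathepsin Ctss (1.60) and the Fc receptor chain Fcer1g (1.44); camera gave adjusted p = 4.18e-12 (adjusted p = 0.0825 with an estimated correlation). Matrix proteases and their inhibitors were higher at 12 of 20 genes and lower at none, adjusted over all genes or over the list alone, among them Adamts9, Timp1 (3.05) and the urokinase receptor Plaur (1.88) (adjusted p = 1.82e-07; adjusted p = 0.0583 with an estimated correlation). Without the 3 libraries that stood apart these lists counted 18, 15 and 10 higher genes. All 7 red cell markers were higher, adjusted over all genes or over the list alone, including the globin Hbb-bt (2.25), the anion exchanger Slc4a1 (2.77) and the haem synthesis enzyme Alas2 (2.39), with adjusted p = 2.37e-07 (adjusted p = 0.198 with an estimated correlation).

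Stress-response lists moved in different directions. The oxidative stress list had 11 of 22 genes higher and none lower (13 and 1 adjusted over the list alone), with haem oxygenase Hmox1 up by 2.83 and glutathione peroxidase Gpx3 by 2.24 (adjusted p = 3.96e-07; adjusted p = 0.0583 with an estimated correlation). Glucocorticoid-response genes were higher at 10 of 16, adjusted either way, but the leaders Lcn2, Angptl4 (2.34) and the metallothioneins Mt2 (2.75) and Mt1 (2.14) are also known to respond to inflammation, lipids or metals (adjusted p = 1.80e-08; adjusted p = 0.121 with an estimated correlation). Apoptosis genes were higher at 10 of 25, led by the death receptor Tnfrsf1a (1.36) and the inhibitor Birc3 (1.15), with 11 higher and 2 lower adjusted over the list alone (adjusted p = 2.92e-04; adjusted p = 0.0504 with an estimated correlation). Heat shock genes went the other way: 10 of 14 were lower and none higher (11 lower adjusted over the list alone), including the co-chaperone Dnaja1 (-1.12), the mitochondrial chaperonin Hspd1 (-0.84), Hsp90ab1 (-0.77) and Hsph1 (-1.54; adjusted p = 1.34e-05 for the list; adjusted p = 0.229 with an estimated correlation).

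Basement membrane genes did not move as one group in GFP-AL. Of 21 tested, 7 were lower, among them Col4a1, Col4a2, Col15a1 (-0.95) and the laminin chain Lama3 (-0.91), and 4 were higher (8 and 4 adjusted over the list alone; 6 and 2 with quantile normalization; camera adjusted p = 0.382). Integrin and adhesion genes were lower at 7 of 24 and higher at 1 (9 and 1 adjusted over the list alone), with Itgav at -1.63 and Itgb3 at -0.76 (camera adjusted p = 0.0628; fry adjusted p = 3.23e-04). Collagen-modifying enzymes split 5 higher and 5 lower of 24 (5 and 6 adjusted over the list alone), with the cross-linking oxidases Lox (1.12) and Loxl2 (0.75) up and the collagen galactosyltransferase Colgalt2 (-0.97) and the prolyl hydroxylase P3h2 (-0.67) down (adjusted p = 0.559, camera direction up although the list median was -0.10).

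Markers of several other cell types moved along with these groups. Choroid plexus and ependymal markers were lower at 12 of 16 genes, adjusted over all genes or the list alone, with medians per GFP-AL library of -1.15 to -0.525 against the GFP-Veh mean; Ttr, the most abundant, went from 5122 ± 2260 to 2648 ± 417 FPKM (camera adjusted p = 3.69e-06; adjusted p = 0.368 with an estimated correlation). Without the 3 libraries that stood apart 7 were lower. Sostdc1 and Kcne2, named above among the lowest genes, are members of this list, and the preparation was meant to clear choroid plexus. Both fell more steeply than Ttr, Sostdc1 from 27.3 to 3.995 FPKM and Kcne2 from 22.1 to 3.99. Both were also highest in GFP-Veh replicate 2, which had the highest Ttr share. Whether remaining choroid plexus accounts for their fall was not tested. Oligodendrocyte markers were lower at 12 of 17 and higher at 1 (13 and 1 adjusted over the list alone), with Ugt8a at -1.99 and Enpp2 at -0.82 (adjusted p = 4.40e-04; adjusted p = 0.532 with an estimated correlation). Smooth muscle markers were lower at 7 of 18, adjusted either way, but at 3 with median-of-ratios scaling and at 1 without those 3 libraries (camera adjusted p = 0.110). Endothelial markers were higher at 9 of 20 and lower at 3 (10 and 3 adjusted over the list alone; 4 and 4 with quantile normalization), with von Willebrand factor Vwf up by 1.70 and the angiopoietin receptor Tek down by 0.95 (adjusted p = 0.0125; adjusted p = 0.609 with an estimated correlation). Neutrophil and lymphocyte markers were higher at 4 of 10 and lower at 1 (4 and 3 adjusted over the list alone; camera adjusted p = 0.0680), including Il1r2 (2.94) and Retnlg (2.18), with uneven medians of -0.375, 2.718, 1.124, -0.156 and 1.628 in GFP-AL replicates 1 to 5. Astrocyte markers were lower at 6 of 16 and higher at 1 (7 and 1 adjusted over the list alone; 4 and 1 with median-of-ratios scaling; camera adjusted p = 0.0556). No neuron marker of 20 passed, over all genes or over the list alone.

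LH3-AL against GFP-AL asked what the LH3 virus changed under the same drugs. The genes lowest in LH3-AL included acute-phase and inflammatory genes. Chil3 averaged 69.3 ± 25.5 FPKM in GFP-AL and 3.20 ± 1.49 in LH3-AL (log2 fold change -4.07 ± 0.34, SE), and the acute-phase protein Saa3 28.2 ± 20.2 and 0.572 ± 0.484 (-4.07 ± 0.38). Tubb6 (-3.55), the secreted hormone Stc1 (-3.55), Cd14 (-3.47), Plaur (-3.47), Serpina3n (-3.32), Ch25h (-3.32), Tnfsf8 (-3.28) and the granulocyte growth factor Csf3 (-3.25) followed. The 10 highest were Cyp2e1 (2.34), Gkn3 (2.33), Kcne2 (2.05), Slc26a10 (2.02), Sostdc1 (2.01), Akr1c14 (1.98), Sgpp2 (1.96), the chemokine Cxcl12 (1.87), the transporter Slc16a4 (1.75) and Prickle1 (1.69). Gkn3 went from 10.1 ± 3.75 to 58.0 ± 32.0 FPKM and Cxcl12 from 39.8 ± 15.8 to 138 ± 32.0. Kcne2 and Sostdc1 are members of the choroid plexus and ependymal list.

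In this comparison 3723 genes passed, 2227 higher and 1496 lower in LH3-AL, and 1768 of them changed at least 1.5-fold; limma adjusted p was at most 7.38e-04 for the 20 named genes. The groups did not overlap at 2539 genes (19.4%; chance gives 0.79%). Median-of-ratios scaling gave 1782 higher and 1895 lower. Without GFP-AL replicates 2 and 3, an alternative chosen after seeing the data, 1951 genes passed, 1859 of them among the 3723.

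Lists of inflammation, matrix proteolysis and stress that rose in GFP-AL were lower in LH3-AL, as were some lists with a weaker or uneven change in GFP-AL. Among the latter, neutrophil and lymphocyte markers had not passed camera in GFP-AL against GFP-Veh (adjusted p = 0.0680). Immediate early genes were higher there at 5 of 24 and lower at 1 (camera adjusted p = 0.00446, and 0.637 with an estimated correlation). Inflammation and leukocyte adhesion genes were lower at 19 of 25 and higher at 1, adjusted over all genes or over the list alone (camera adjusted p = 1.07e-12; adjusted p = 0.0485 with an estimated correlation). Matrix proteases and inhibitors were lower at 12 of 20 (13 adjusted over the list alone), with Adamts9 at -3.16, Timp1 at -2.58 and Adamts1 at -2.78 (adjusted p = 1.19e-09; adjusted p = 0.0462 with an estimated correlation). Oxidative stress genes were lower at 11 of 22 (17 adjusted over the list alone; adjusted p = 2.07e-07; adjusted p = 0.0485 with an estimated correlation) and apoptosis genes lower at 9 of 25 and higher at 1 (10 and 1 adjusted over the list alone; 5 and 0 without the 3 libraries that stood apart; adjusted p = 2.15e-04; adjusted p = 0.0462 with an estimated correlation). Microglia and macrophage markers were lower at 15 of 19 (16 adjusted over the list alone), with Ctss at -1.65 and Cd68 at -0.99 (adjusted p = 1.83e-12; adjusted p = 0.0760 with an estimated correlation). Neutrophil and lymphocyte markers were lower at 6 of 10, adjusted either way, including Il1r2 (-2.96) and Retnlg (-3.20; adjusted p = 9.67e-05 for the list; adjusted p = 0.475 with an estimated correlation). Immediate early genes were lower at 13 of 24 (15 adjusted over the list alone), with Fosl1 at -2.84, and at 8 without the 3 libraries that stood apart. The list had camera adjusted p = 1.05e-08, and 0.409 with an estimated correlation. Medians against the GFP-Veh mean were 0.691 and 0.072 in LH3-AL replicates 1 and 2, above those in GFP-AL replicates 1 and 5 (-0.161 and -0.299). LH3-AL replicates 3 to 5 lay below every GFP-AL library. Proteasome subunits were lower at 13 of 26 (18 adjusted over the list alone; adjusted p = 1.37e-08; adjusted p = 0.475 with an estimated correlation). Their medians were -0.164 to -0.043 in LH3-AL and 0.124 to 0.415 in GFP-AL. GFP-Veh replicate 2, at 0.451, lay above every GFP-AL library.

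Choroid plexus and ependymal markers were higher at 10 of 16 in LH3-AL (11 adjusted over the list alone; adjusted p = 4.12e-05; adjusted p = 0.475 with an estimated correlation) and oligodendrocyte markers higher at 8 and lower at 1 of 17 (11 and 1 adjusted over the list alone; 4 and 1 without the 3 libraries that stood apart; adjusted p = 0.0202; adjusted p = 0.645 with an estimated correlation). Oligodendrocyte medians per library against the GFP-Veh mean overlapped between the groups. They ran from -0.689 to 0.414 in LH3-AL and from -1.379 to -0.557 in GFP-AL. Basement membrane genes were higher at 7 of 21 and lower at 2 (8 and 2 adjusted over the list alone; camera adjusted p = 0.101; fry adjusted p = 0.0109), led by Col4a1, Col4a2, Lama3 (1.14) and Col15a1 (0.91). Collagen-modifying enzymes were higher at 3 of 24 and lower at 5, adjusted over all genes or over the list alone (camera adjusted p = 0.288), with Lox at -1.05, Loxl2 at -0.70 and Colgalt2 at 0.96. No red cell marker of 7 passed, over all genes or over the list alone (list median -0.44; adjusted p = 0.127), and 2 heat shock genes of 14 were lower and 1 higher (4 and 1 adjusted over the list alone; adjusted p = 0.127).

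LH3-AL against GFP-Veh asked how far vessels with both the LH3 virus and the drugs differed from the control vessels. The genes that differed included 3 red cell markers and 8 heat shock genes. Lrg1 averaged 17.3 ± 13.7 FPKM in GFP-Veh and 89.7 ± 38.8 in LH3-AL (log2 fold change 2.49 ± 0.45, SE). Also among the highest were Alas2 (1.95), Hbb-bt (1.91), the clock-controlled transcription factor Dbp (1.78), the red cell enzyme Bpgm (1.55), Fam46c (1.52), Ube2c (1.36) and the pseudogene Cyp4b1-ps2 (1.20). The lowest were the inducible chaperones Hspa1a (34.4 ± 11.9 against 4.86 ± 2.36 FPKM; -2.58 ± 0.40) and Hspa1b (-2.52), the stress-induced factor Atf3 (-2.17), Hspa1l (-1.66), Plaur (-1.59), Hsph1 (-1.44), Asb4 (-1.35), the shear-responsive factor Klf2 (-1.34), the cell cycle inhibitor Cdkn1a (-1.22) and the phosphatase Dusp8 (-1.21). Hspa1a and Hspa1b are near-identical neighbours, as are the beta-globin genes, and how reads were assigned between such copies is not given in the sources used here.

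Only 68 genes passed here (limma), 19 higher and 49 lower in LH3-AL, with 1180 at an unadjusted p under 0.05; the groups did not overlap at 611 genes (4.67%; chance gives 0.79%). This count moved with the fit, from 4 genes with log2 depth as a covariate to 1195 with array weights. In a fit of only these 2 groups 176 genes passed. The main fit estimates the residual variance of each gene over all groups, so the spread of the GFP-AL libraries bears on this count. Of the genes named here, Alas2, Cdkn1a, Fam46c, Cyp4b1-ps2 and Klf2 lost their call in most of the 15 fits that each left out 1 library, whereas Dbp, Atf3, Hspa1a, Hspa1b, Hspa1l, Hsph1 and Dusp8 kept theirs in each of those. None of the 4 genes called with depth as a covariate was higher in LH3-AL, and of the 10 highest and 10 lowest genes only Dusp8 was among them.

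Heat shock genes were lower at 8 of 14 and higher at none in LH3-AL (12 lower adjusted over the list alone), with Dnaja1 at -1.13, Hspd1 at -0.70 and Hsp90ab1 at -0.71; this list passed camera (adjusted p = 3.35e-26) and also with an estimated correlation (adjusted p = 0.00923). Medians per library were -0.846 to -0.65 in LH3-AL, -0.926 to -0.344 in GFP-AL and -0.11 to 0.163 in GFP-Veh. Red cell markers were higher at 3 of 7 (7 adjusted over the list alone; adjusted p = 1.68e-14; adjusted p = 0.0957 with an estimated correlation), and at 6 without the 3 libraries that stood apart. Immediate early genes were lower at 4 of 24 and higher at 1 (7 and 1 adjusted over the list alone), with Klf6 at -0.83 and Klf4 at -1.18 beside Atf3 and Klf2 (adjusted p = 3.37e-05; adjusted p = 0.916 with an estimated correlation). The medians of this list were 0.691 and 0.072 in LH3-AL replicates 1 and 2 and -0.937, -1.184 and -1.102 in replicates 3 to 5, so not every library was below GFP-Veh. Of 24 genes of angiotensin, endothelin and nitric oxide signalling 2 were higher and none lower (3 and 0 adjusted over the list alone), angiotensin-converting enzyme Ace (0.64) and endothelin Edn1 (0.62), and the list did not pass camera (adjusted p = 0.356). No gene of the inflammation list passed over all genes, and 3 of 25 were higher adjusted over the list alone; no microglia, oligodendrocyte, choroid plexus or basement membrane gene passed either way. Camera called the inflammation list up (adjusted p = 0.0106), the oligodendrocyte list down (0.0106) and the basement membrane list up (0.0358), each with adjusted p = 0.916 with an estimated correlation. No neutrophil or lymphocyte marker of 10 passed over all genes and 5 were lower adjusted over the list alone (camera adjusted p = 4.59e-05; adjusted p = 0.916 with an estimated correlation).

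**Figure D3:**
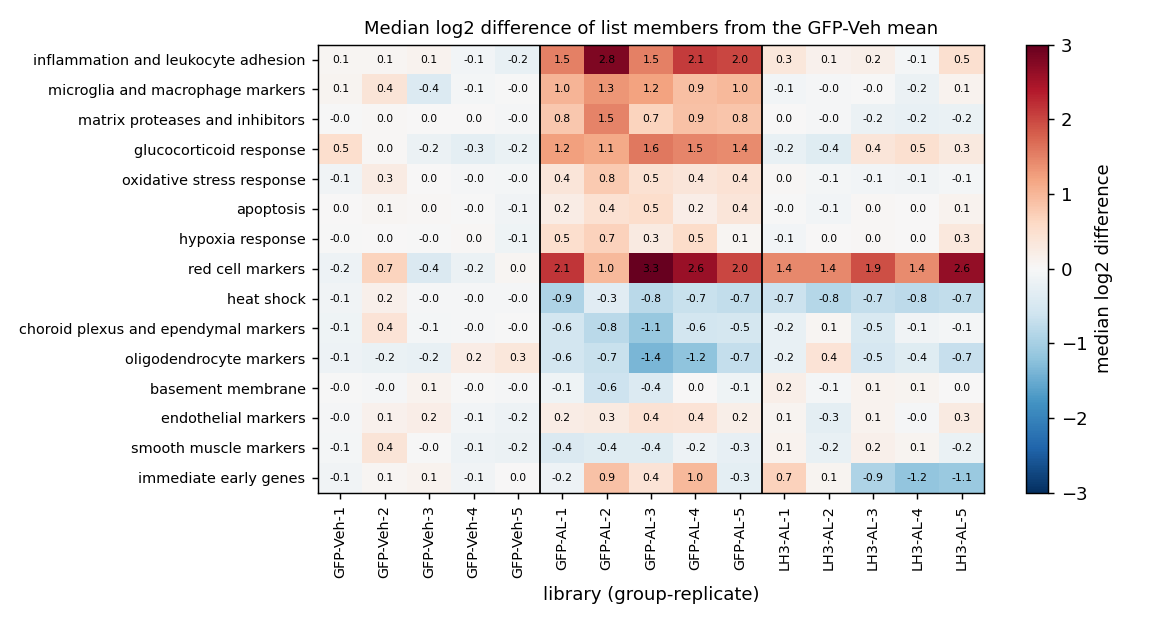
Median log2(FPKM + 1) difference of each list's members from the GFP-Veh mean (rows, lists; columns, libraries; colour and printed digits, the median). Inflammation medians reach 1.5 to 2.8 in GFP-AL and stay at 0.48 or less in LH3-AL, whereas heat shock medians lie at -0.65 or less in each LH3-AL library.

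Genes changed in GFP-AL were then followed into LH3-AL. Without an LH3 virus group given saline, a move back cannot be told from a change that the virus makes without the drugs. Of the 3737 genes called in GFP-AL against GFP-Veh, 99.04% had the opposite sign in LH3-AL against GFP-AL, with a median move back of 0.50 against a median change of 0.58. In LH3-AL replicates 1 to 5 the median move back was 0.57, 0.60, 0.44, 0.51 and 0.39. By limma, 2635 (70.5%) were called in the opposite direction and 4 in the same direction. Chil3, Saa3, Tubb6, Stc1, Cd14, Plaur, Serpina3n, Ch25h, Tnfsf8 and Csf3 moved back the most. Plaur ended below GFP-Veh, and Serpina3n remained at 38.5 ± 27.2 FPKM against 10.4 ± 2.52 in GFP-Veh (log2 difference 1.47, adjusted p = 0.2004, not called). Still called against GFP-Veh in LH3-AL, in the same direction as in GFP-AL, were 40 of the 3737 genes.

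Both comparisons use the GFP-AL libraries, which alone pushes signs apart. With no effect simulated in any group, 66.8% of genes had opposite signs, against 84.9% of the 13082 tested. In simulated data with LH3-AL equal to GFP-AL, 60.1% of called genes had opposite signs. The simulated noise was independent between genes, so shifts that genes share in a library are not part of these shares. When the GFP-AL libraries were split so that each comparison had its own, a median of 95.1% of called genes went back over 20 splits (88.0 to 98.6%), against 50.8% in the simulation with LH3-AL equal to GFP-AL. The median move back was then 0.59, and the remaining GFP-AL libraries differed from GFP-Veh by a median of 0.71 at the same genes. Lists of 3737 and 3723 genes drawn independently would share 557 genes in opposite directions. Simulated unchanged groups shared none, but with a mean of 0.1 genes called in GFP-AL against GFP-Veh they could hardly share any. The correlation of the log2 fold changes was -0.879 (simulated -0.4997) and their covariance -0.211 (simulated -0.0162); with split libraries these were -0.697 and -0.185. The changes of GFP-AL and LH3-AL against GFP-Veh correlated at 0.327 (simulated 0.501) with a covariance of 0.0396 (simulated 0.0162), and at 0.247 with a covariance of 0.0329 when the GFP-Veh libraries were split. These correlations are across genes, which are not independent replicates.

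**Figure D4:**
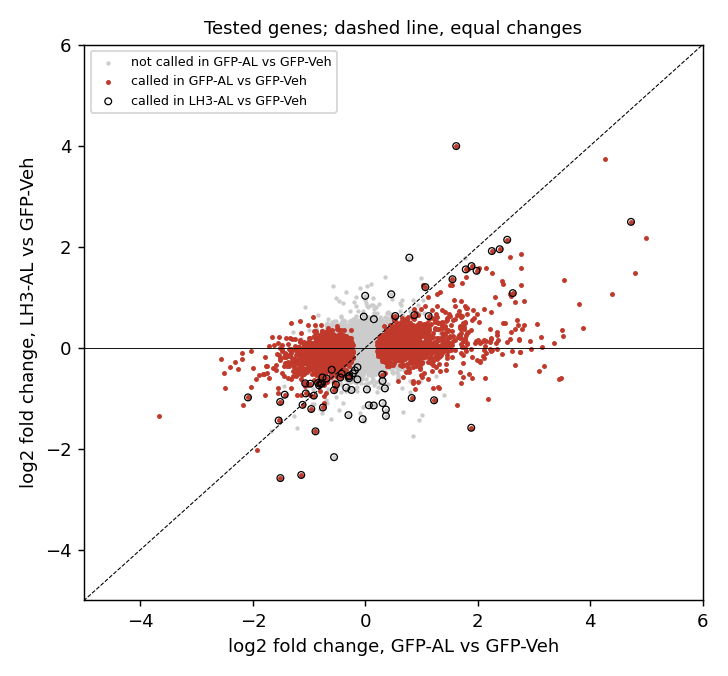
Log2 fold change against GFP-Veh of each tested gene in GFP-AL (x axis) and LH3-AL (y axis); red points were called in GFP-AL against GFP-Veh (3737 genes), open circles in LH3-AL against GFP-Veh (68 genes), and the dashed line marks equal changes. Of the red points, 40 are also circled with the same sign on both axes.

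The authors' deposited table for GFP-AL against GFP-Veh listed 1764 genes, 863 higher and 901 lower. Its log2 fold changes matched the ratio of group mean FPKM for that contrast (Pearson r = 1.00 over 1758 genes, median absolute difference 0.0058). The authors' deposited table named for LH3-AL against GFP-Veh listed 1746 genes, 916 higher and 830 lower. Its log2 fold changes matched LH3-AL against GFP-AL instead (r = 1.00 over 1741 genes, median absolute difference 0.0059), with r = 0.137 and a median absolute difference of 1.44 for the contrast in its name. It was therefore compared with LH3-AL against GFP-AL. Of the genes in the authors' deposited table for GFP-AL against GFP-Veh, 1072 were tested here and 1028 (95.9%) were called in the same direction. For the authors' deposited table of LH3-AL, 995 were tested and 949 (95.4%) were called in the same direction. In the authors' deposited tables Col4a1 stood at -1.17 and 1.33, and Plod3 was in neither. Those tables hold only absolute log2 fold changes above 1, and Plod3 changed by less here (-0.25 and 0.60), so its absence says nothing about its significance.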

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

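The tests without the libraries that stood apart, of depth for GFP-AL against GFP-Veh, and of resident microglia and cold-induced genes were devised after the counts of called genes had been seen, before their own values were. Those of blood-derived myeloid genes, of depth for LH3-AL against GFP-AL and for heat shock genes, and of clock genes were chosen only after the result, or part of it, was seen. The heat shock test replaced an earlier one that rested on GFP-Veh replicate 5 alone (list median -0.037), and the clock test was narrowed to Dbp after its result was known.

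In 29 of 276 groups of 5 libraries, 1 library lay far from the other 4, with a gap to the nearest that was a large part of the whole range; chance gives about 5%. The ratio of gap to range is given for each. In GFP-Veh replicate 2 it was 0.774 for the globin share, 0.769 for the Ttr share, 0.8 for choroid plexus markers, 0.711 for heat shock genes and 0.761 for the proteasome list, all highest, and 0.731 for Plod2, lowest. In GFP-Veh replicate 5 it was 0.849 for depth, 0.779 for the mitochondrial share and 0.736 for mitochondrially encoded genes, all highest. GFP-Veh replicate 3 was lowest for Myoc (0.85) and highest for Stc1 (0.72) and the basement membrane list (0.841). GFP-Veh replicate 1 was lowest for Hspa1a (0.721) and Atf3 (0.723).

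In GFP-AL replicate 2 the ratio was 0.712 for Saa3, 0.757 for matrix proteases and 0.769 for oxidative stress genes, all highest, and 0.825 for Alpl and 0.835 for Dbp, both lowest. GFP-AL replicate 1 was lowest for Serpina3n (0.731) and GFP-AL replicate 4 highest for Col4a2 (0.718). LH3-AL replicate 1 was highest for Cyp2e1 (0.711), Hspa1a (0.717) and Hspa1l (0.907) and lowest for the ribosomal protein list (0.786). LH3-AL replicate 5 was highest for Adamts9 (0.878), Tubb6 (0.717), the hypoxia list (0.715) and the cell cycle list (0.905).

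GFP-AL differed from both other groups at far more genes than these differed from each other. Of 100 splits of the 10 libraries of each comparison only the real one, 1 of 100 each time, gave as many genes. These were 3737, 3723 and 68, with 2040, 50 and 1 as the highest of the other splits. That is the smallest share that 100 splits can give, so chance is made unlikely but is not excluded. The split with 2040 genes exchanged GFP-Veh replicate 2 and GFP-AL replicate 5 and still parts most libraries by group, which points to a structure of the samples. Without GFP-AL replicates 2 and 3 the GFP-AL against GFP-Veh count was 14.8 times the LH3-AL against GFP-Veh count. This argues against those 2 libraries as the whole cause. The LH3-AL against GFP-Veh count rose with array weights, so the size of this ratio depends on the fit. With depth as a covariate the median change of called genes was 106.1% of its size in GFP-AL against GFP-Veh and 99.2% in LH3-AL against GFP-AL, and 108.4% and 99.5% without GFP-Veh replicate 5. In the first, 2249 of 3737 genes stayed called as the median SE rose from 0.143 to 0.184, and 6 without GFP-Veh replicate 5 (0.305). The other GFP-Veh libraries were shallower than every GFP-AL library, so without replicate 5 the test cannot tell depth from group there. In LH3-AL against GFP-AL 3387 of 3723 genes stayed called, and 2954 without GFP-Veh replicate 5, which argues against depth as the whole cause there. Depth as a reason for the low count of 68 stays open. With separate GFP-AL libraries in each comparison 95.09% of called genes still went back, which argues against the shared libraries as the whole cause. A batch shared by the GFP-AL libraries, for which the labels give no date, stays open, as do the drugs and the LH3 virus.

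Inflammatory genes were higher in GFP-AL. More resident microglia as the cause is argued against by their marker genes, with a median log2 fold change of 0.1515 and 1 of 9 called. Blood-derived myeloid genes had a median of 1.4968 without the gene named elsewhere, with 5 of 6 called, so more such cells may be part of it. In GFP-Veh these 6 genes ranged from 0.934 (Fcgr4) to 112.5 FPKM (Lyz2), so some were expressed without the drugs. Their rise therefore cannot tell incoming cells from a change in cells already there. Activated endothelial genes, a set written after some of its values were seen, were called higher at 7 of 8. Without Ackr1 and Lrg1, named above among the largest gains, 5 of 6 were called, and these include Vwf, named above as an endothelial marker. Whether the set rose apart from myeloid cells was not tested. Whether cell numbers or expression per cell changed cannot be decided from bulk RNA, and no cell sorting is given in the sources used here.

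Heat shock genes were lower in LH3-AL than in GFP-Veh, and in GFP-AL as well. With depth as a covariate the list median was -0.6875 against -0.7491 without it, and 14 of 14 genes were lower; calls went from 8 to 1 while the median SE rose from 0.142 to 0.188, so the calls ended through a wider error more than a smaller change. Without GFP-Veh replicate 5 the median change kept 89.4% of its size and 0 genes were called (median SE 0.319). The other GFP-Veh libraries were shallower than every LH3-AL library, so without replicate 5 the test cannot tell depth from group, and depth stays open. The cold-induced genes Cirbp and Rbm3 differed by a mean of 0.2872, between the bounds set in advance, so a lower body temperature at collection stays open. In GFP-AL against GFP-Veh, where heat shock genes were lower too, both were called higher with a mean of 0.791, so it stays open there as well. Other differences in handling between groups were not tested.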

How the results depend on the processing

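The fits with depth as a covariate, with voom and without 2 or 3 libraries that stood apart were chosen only after the data were seen. Of 2068 comparisons of 74 values of named genes with an alternative, 1901 kept direction and side of the threshold, 146 no longer passed, 9 newly passed and 12 changed sign. The counts of 3737 and 3723 genes (GFP-AL against GFP-Veh, LH3-AL against GFP-AL) became 2174 and 2109 with a mean of at least 5 FPKM and 1854 and 1768 at 1.5-fold or more, as fewer genes could pass. The first became 2352 with depth as a covariate, as the median SE of called genes rose from 0.143 to 0.184 while their median change did not shrink (0.583 and 0.618). The other became 1951 without GFP-AL replicates 2 and 3; the cause was not tested. The 68 genes of LH3-AL against GFP-Veh became 31 with the replicate number as a factor, 1195 with array weights and 176 with only the 2 groups. They became 170 and 158 without 2 or 3 libraries that stood apart, and 4 with depth as a covariate. GFP-AL libraries enter this comparison only through the residual variance, which is estimated over all groups. The rises to 176 with only the 2 groups and to 170 without GFP-AL replicates 2 and 3 therefore came through that variance. The cause of the other changes was not tested. Of the 68, 68 were among the 1195 and 29 among the 31. With 1 library left out, counts ran from 2840 to 4437, from 2658 to 4291 and from 27 to 110. The count of 68 moved by over 1.5 times without GFP-Veh replicate 1 (40), 3 (29), 4 (27) or 5 (34), GFP-AL replicate 2 (110), or LH3-AL replicate 2 (44), 3 (27), 4 (30) or 5 (40). Plod3 in LH3-AL against GFP-AL ran from 0.55 to 0.63, the share going back from 98.58 to 99.30% (95.09% with split libraries), and the overlaps with the authors' deposited tables from 985 to 1028 and from 888 to 955. Those overlaps were 1591 and 1491 with no filter and 479 and 422 at 5 FPKM or more, as more or fewer genes were tested. List calls with an estimated correlation were 0, 4 and 1. Signs changed for Plod1 in LH3-AL against GFP-AL (0.0229 with quantile normalization, 0.0116 and 0.0036 without GFP-AL replicate 1 or 4, 0.0009 and 0.0091 without LH3-AL replicate 1 or 3; lowest -0.0349). They changed for Plod2 in GFP-AL against GFP-Veh (0.0624, 0.0105 and 0.0012) and LH3-AL against GFP-AL (-0.1093, -0.1093 and -0.0481) without 2 or 3 libraries that stood apart or without GFP-AL replicate 3, against -0.2854 and 0.2385 without GFP-AL replicate 4, and for Col4a1 in LH3-AL against GFP-Veh (-0.0009 without LH3-AL replicate 5, 0.248 without replicate 2); none of these was called. Replicate numbers did not pair the libraries: correlations between libraries of the same number ran from -0.261 to 0.286, and 4 of 15 libraries matched best with their own number. In simulated data of this size 37.5% of genes changed by 0.5 on the log2 scale were recovered, so small changes can be missed.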

Other observations

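The clock gene test was chosen after Dbp had been seen to differ, and it was narrowed to Dbp only after its result was seen. Dbp was higher in LH3-AL than in GFP-Veh. Other clock genes in phase with Dbp had a median log2 fold change of 0.5401 in that comparison and those of opposite phase a median of -0.5444; 1 of 8 and 0 of 4 were called. In GFP-AL against GFP-Veh the medians were 0.372 and -0.776, with 2 of 8 called higher and 3 of 4 called lower (1 higher). A different time of day at collection is therefore a candidate explanation for Dbp, and it is not excluded for GFP-AL against GFP-Veh, while an effect of the treatments on the clock stays open. Arntl, which peaks opposite to Dbp, stood at 28.8, 20.8, 7.99, 8.72 and 8.36 FPKM in LH3-AL replicates 1 to 5, at 22.9 to 29.1 in GFP-Veh and at 7.95 to 14.4 in GFP-AL. Immediate early gene medians were 0.69, 0.07, -0.94, -1.18 and -1.10 in those LH3-AL libraries, whereas heat shock medians were between -0.846 and -0.65 in each of them.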
